A study of Talaromyces verruculosus with 6 samples.

How the data were processed

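RNA from mycelia grown with or without pectin was sequenced in 3 control and 3 pectin libraries, from poly-T purified mRNA read as paired ends, per the labels' protocols. The series' design text calls the samples biological replicates. The aligner, the counting tool, its use of strand and the name of the genome build are not given in the sources used here; the contig names and locus tags are those in the files. Per the file headers, the deposited files give read counts per gene for exons, exon-exon junctions and introns, in total and for uniquely mapped reads. In the files, exon and intron counts add up to the gene count, and intron reads are also listed for genes with 1 exon, so the intron count is called reads outside annotated exons. Per the file headers the authors also deposited RPKM, which was used for levels after removing digit separators. The deposited fraction of unique reads and of intron reads per gene was recomputed from the counts. The TPM columns were not used. Annotated lengths are 100% multiples of 3, so the models hold no UTRs and lengths are coding lengths. Annotated neighbours overlap in 0 cases. Counting without known strand cannot separate a gene from antisense transcription.

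Total exon reads were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood with robust estimation, TMM factors and filterByExpr by group, which kept 9177 genes and left out 2149. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. The common dispersion corresponds to a biological coefficient of variation of 26.7%. TMM factors were 1.183, 1.024 and 1.027 in controls 1 to 3 and 0.9033, 0.945 and 0.9424 in pectin 1 to 3. Unique reads made up 99.991% to 99.9972% of exon reads. Counts of libraries of one group differed by far more than sampling noise, with a chi-square per degree of freedom of 32.4 to 129.7, so no pair of files held one library deposited again; this says nothing of how separate the cultures were. No labels give batches. Counts were simulated for pectin against control from the real means and library sizes (9115 genes, 50 changed genes per size). On these the test recovered 36% of 2-fold, 90% of 4-fold, 98% of 8-fold and 96% of 16-fold changes. Changed genes that the filter left out counted as not recovered. The test made 17 false calls among 8919 unchanged genes, beside 18, 45, 49 and 48 true calls in order of size. False calls thus took a larger share of all simulated calls than the threshold of 0.05.

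The test, its samples and the rule for named genes were set before the data were examined, with alternatives in scaling, filter, test, threshold, replicate block and left-out libraries. The rule took the changed genes (at least 2-fold) that were most abundant by mean CPM in either group; since no descriptions are paired with the tags, at most 2 tags per direction are given. For the same reason the 26 gene lists fixed beforehand, with their counts, set tests and read shares, could not be applied. Runs of neighbours, gene structure, reads outside exons, the comparison of 16-fold changes and the alternatives with unique exon reads, total gene reads and without control 1 and pectin 1 were added after the data had been seen. Also looked at, and not used further, were correlations of each library's deviation with coding length, exon number and level, and control 3 against the other controls in genes that rose.

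Neighbouring pairs were compared with 100000 random placements of the calls among tested genes (Python 3.11.15, numpy 2.4.6). On simulated placements without clustering, this test gave p under 0.05 in 2 of 20 runs, and p = 0.00498, the smallest that its 200 placements give one-sided, with 31 planted runs of 3 genes (permutation test, 9177 genes). The share of reads outside exons was tested with edgeR as an interaction of read type and group, with library as a block, in 8062 genes with at least 60 reads of each type. Each read type was scaled to its own total in each library, so a gene's change is relative to the shift over whole libraries. On simulated counts for pectin against control with an assumed dispersion, it recovered 97.5% of 200 genes changed 4-fold among 8000 genes and made 7 false calls. Only reads outside exons were drawn, around the real exon reads, so noise in exon reads was left out. Smaller changes were not simulated. Recovery and false calls in the data may therefore differ from these. Further tools were DESeq2 1.42.0, limma 3.58.1 and matplotlib 3.10.9. A comparison of 3 libraries with 3 cannot give an exact permutation p under 0.1.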

Results

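The transcriptome of actively growing mycelia of Talaromyces verruculosus strain TS63-9, a filamentous fungus, was measured by sequencing of poly-A selected RNA. Pectin, a galacturonic acid-rich polysaccharide of plant cell walls, was given at 5 g/L in 3 cultures and left out of 3 control cultures, and RNA was taken after 24 h. Between 10320372 and 11393959 reads fell on annotated exons per library, with means of 10919000 ± 532445 in control and 11030200 ± 354684 in pectin libraries (SD, n = 3 each). Reads were found for 10394 to 10548 of the 11326 annotated genes in each library. A count of 0 in a control library allows up to about 0.275 CPM (read counts scaled to a common library total), the value of 3 reads, and covers counting error only. The first principal component of log2 CPM took 67.1% of the variance and set the 3 pectin libraries apart from the 3 controls. The second took 20.1% and set control 1 and pectin 1 apart from control 3 and pectin 3.

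The design asks which genes mycelia express more or less strongly when pectin is present. Of 9177 genes tested, 844 were higher and 642 were lower with pectin at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 558 were at least 2-fold higher and 504 at least 2-fold lower. Large changes were mostly rises. At least 16-fold changes were found in 108 genes that rose and 11 that fell, and at least 64-fold changes in 36 and 1, by fitted fold changes. Genes at least 2-fold higher took 4.28 ± 0.413% of exon reads in control and 13.2 ± 1.06% in pectin libraries (SD, n = 3 each). Genes at least 2-fold lower went from 4.62 ± 1.36% to 1.23 ± 0.0375% (SD, n = 3 each). These shares describe genes chosen by the same test. The 10 most abundant of the genes that were at least 2-fold higher went from 1.05 ± 0.156% to 3.97 ± 0.309% of exon reads. In control libraries 150 of the 558 genes averaged under 1 RPKM, and 127 of the 504 genes that fell did so with pectin. Among the genes that rose, 4 had 0 reads in all 3 controls, and their rises were at least 4.41-fold to at least 91.2-fold, measured against 3 reads per library. With these genes at that floor, 107 rather than 108 genes were at least 16-fold higher, and 34 rather than 36 at least 64-fold higher.

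The number of genes called depended on single libraries. Without control 2 there were 332 higher and 328 lower, without pectin 1 there were 420 and 307, without pectin 2 there were 325 and 190, and without pectin 3 the number of lower genes was 419. Scaling by library size alone, which moved the median log2 fold change of all tested genes to −0.21 from −0.0061, gave 545 higher and 942 lower genes, so that the share of higher genes among all called went from 56.8% to 36.7%. At 2-fold or more this scaling gave 386 higher and 708 lower genes, and upper-quartile factors gave 486 and 571. Which direction had more genes thus depended on the scaling.

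**Figure D1:**
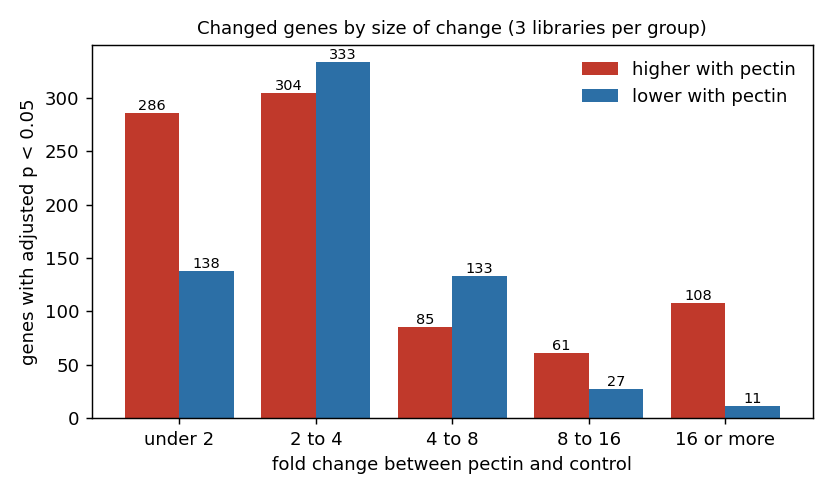
Number of genes with an adjusted p under 0.05 (y axis) in 5 classes of fold change between pectin and control (x axis), 3 libraries per group. Red bars are genes higher with pectin and blue bars genes lower, by fitted fold changes; 108 genes (107 with genes without control reads at the floor) were at least 16-fold higher and 11 at least 16-fold lower.

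The files do not pair the locus tags with gene names, so the most abundant changed genes are given by tag, with positions on the contigs named in the files. ZTR_09821, on LHCL01000118 from 49826 to 52065 on the plus strand with 3 exons, had the highest abundance among the changed genes with pectin. It averaged 56.1 ± 53.7 RPKM in control and 3951 ± 453 RPKM in pectin libraries (SD, n = 3 each), a log2 fold change of 6.25 with a standard error of 0.78 (edgeR adjusted p = 0.00284), and 3 of 3 pectin libraries lay above every control. Control 3 had 118 RPKM of this gene against 22.5 in control 1 and 27.8 in control 2, and without control 3 the log2 fold change was 7.43. ZTR_00191, on LHCL01000005 from 583698 to 585508 on the minus strand with 7 exons, went from 1951 ± 337 to 3539 ± 258 RPKM (SD, n = 3 each), a log2 fold change of 1.01 with a standard error of 0.25 (edgeR adjusted p = 0.0321). Its call was lost with library size scaling (edgeR adjusted p = 0.0574) and without any one of control 2, control 3, pectin 1, pectin 2 or pectin 3, where edgeR's adjusted p was 0.12 for control 2, 0.0572 for control 3, 0.0993 for pectin 1, 0.111 for pectin 2 and 0.0575 for pectin 3. Over all alternatives its adjusted p ran from 8.1e-06 to 0.176.

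ZTR_03362, on LHCL01000022 from 238867 to 240778 on the minus strand with 3 exons, fell from 922 ± 162 to 112 ± 52.3 RPKM (SD, n = 3 each). Its log2 fold change was −2.90 with a standard error of 0.35 (edgeR adjusted p = 0.00243). ZTR_03733, on LHCL01000010 from 356207 to 356850 on the minus strand with 3 exons, went from 2294 ± 497 to 959 ± 233 RPKM (SD, n = 3 each), a log2 fold change of −1.10 with a standard error of 0.26 (edgeR adjusted p = 0.0274). Its call was lost without control 2, pectin 2 or pectin 3, where edgeR's adjusted p was 0.0747, 0.118 and 0.0838, in a range of 0.000313 to 0.133 over all alternatives.

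**Figure D2:**
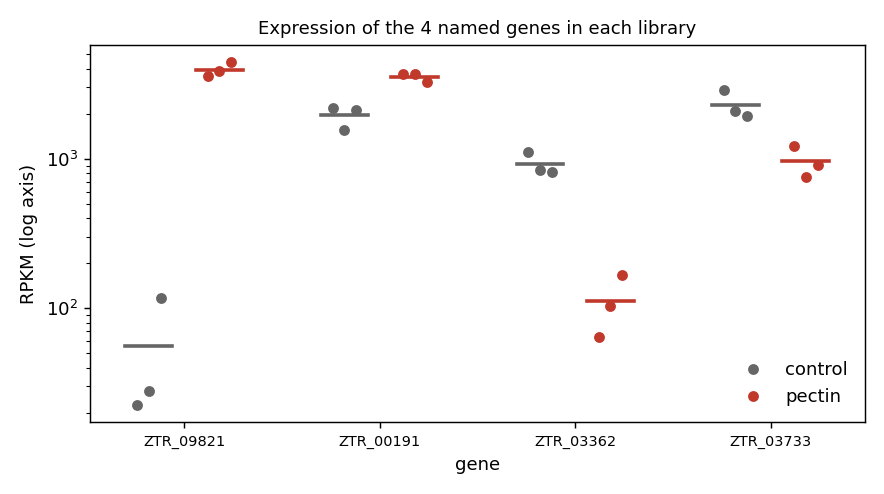
RPKM on a log axis (y) of the 4 named genes (x) in each library. Points are the 3 control (grey) and 3 pectin (red) libraries and bars their means; ZTR_09821 averaged 56.1 RPKM in control and 3951 RPKM in pectin libraries.

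Genes that changed lay side by side in many places. Runs of at least 3 consecutive annotated genes, all at least 2-fold changed in one direction, numbered 23 for genes that rose and 18 for genes that fell, and held 92 of 558 (16.5%) and 71 of 504 (14.1%) of them. The definition of a run, and the regions named here, were chosen after the values were seen. Without control 2 there were 14 and 10 runs, without pectin 2 there were 13 and 6, and the runs that fell numbered 9 without pectin 1 and 11 without pectin 3. The run with the most genes held 8 on LHCL01000118 from 31029 to 60173, up to the last annotated gene of that contig, and included ZTR_09821. Its median change was 57.1-fold, and its summed RPKM went from 119 ± 104 in control to 6905 ± 901 with pectin (SD, n = 3 each), or 1.73 ± 0.176% of exon reads. Without control 3 its median log2 rise went from 5.84 to 6.94. With all libraries its single genes had log2 rises from 1.72 to 6.25. A run of 7 genes on LHCL01000066 from 131297 to 161735 rose by a median of 14.6-fold, or 3.87 on the log2 scale, which was 4.50 without control 3. Single genes in it had log2 rises from 1.09 to 4.37. A run of 7 on LHCL01000128 from 899 to 18937 rose by a median of 13.1-fold. On LHCL01000195 all 4 annotated genes, from 91 to 14597, rose by a median of 37-fold. Summed RPKM in control 3 was 4.4 times that in control 1 in the run on LHCL01000118, 2.95 times on LHCL01000128 and 4.28 times on LHCL01000195. It was 1.78 times on LHCL01000066. The rising runs on LHCL01000003 and LHCL01000012, described below, went the other way, at 0.666 and 0.665 times on LHCL01000003 and 0.425 times on LHCL01000012.

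Of the 6 runs of at least 5 genes that rose, 3 had summed levels under 3 RPKM in control. The 6 genes on LHCL01000003 from 1258651 to 1272853 went from a summed 2.68 ± 0.576 to 154 ± 46.0 RPKM (SD, n = 3 each), with a median rise of 103-fold, or 6.69 on the log2 scale, which was 5.92 without control 2 and 8.20 with a filter of 10 CPM. Its single genes were unlike, with log2 rises from 1.33 to 9.67. The 5 genes on the same contig from 1225485 to 1239871 went from 1.51 ± 0.370 to 165 ± 61.3 RPKM, with a median of 91.2-fold when the 2 genes without reads in controls were set at the floor. The 5 genes on LHCL01000012 from 87947 to 96667 went from 0.497 ± 0.329 to 91.5 ± 37.0 RPKM, with a median log2 rise of 6.95 and 1 gene at the floor; without control 1 the median was 7.94, and with total gene reads 6.25. The 5 runs of at least 5 genes that fell had smaller median changes than these 6. The 7 genes on LHCL01000001 from 255544 to 274568 fell by a median of 1.94 on the log2 scale, from a summed 454 ± 206 to 116 ± 18.6 RPKM. On LHCL01000109, 7 genes from 23770 to 44686 fell by 2.09 and 5 genes from 2290 to 21627 fell by 2.06 on the same scale. The 5 genes on LHCL01000033 from 216834 to 225190 fell by 2.16 and the 5 on LHCL01000042 from 179649 to 206124 fell by 1.97. In each of these runs that fell, control 1 had the highest summed RPKM of the controls, and the medians were smaller without it. They were then −1.58 on LHCL01000001, −1.84 on LHCL01000109 from 23770 and −1.825 from 2290, and −1.73 on LHCL01000042. On LHCL01000033 the median was −1.23 without control 1, −1.23 without control 1 and pectin 1 together and −1.25 with a filter of 10 CPM. Without pectin 2, 0 of the 5 genes on LHCL01000033, 1 of the 5 on LHCL01000109 from 2290 to 21627 and 3 of the 7 on LHCL01000001 remained called at 2-fold by edgeR; the median changes were then −1.96, −1.93 and −1.81.

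**Figure D3:**
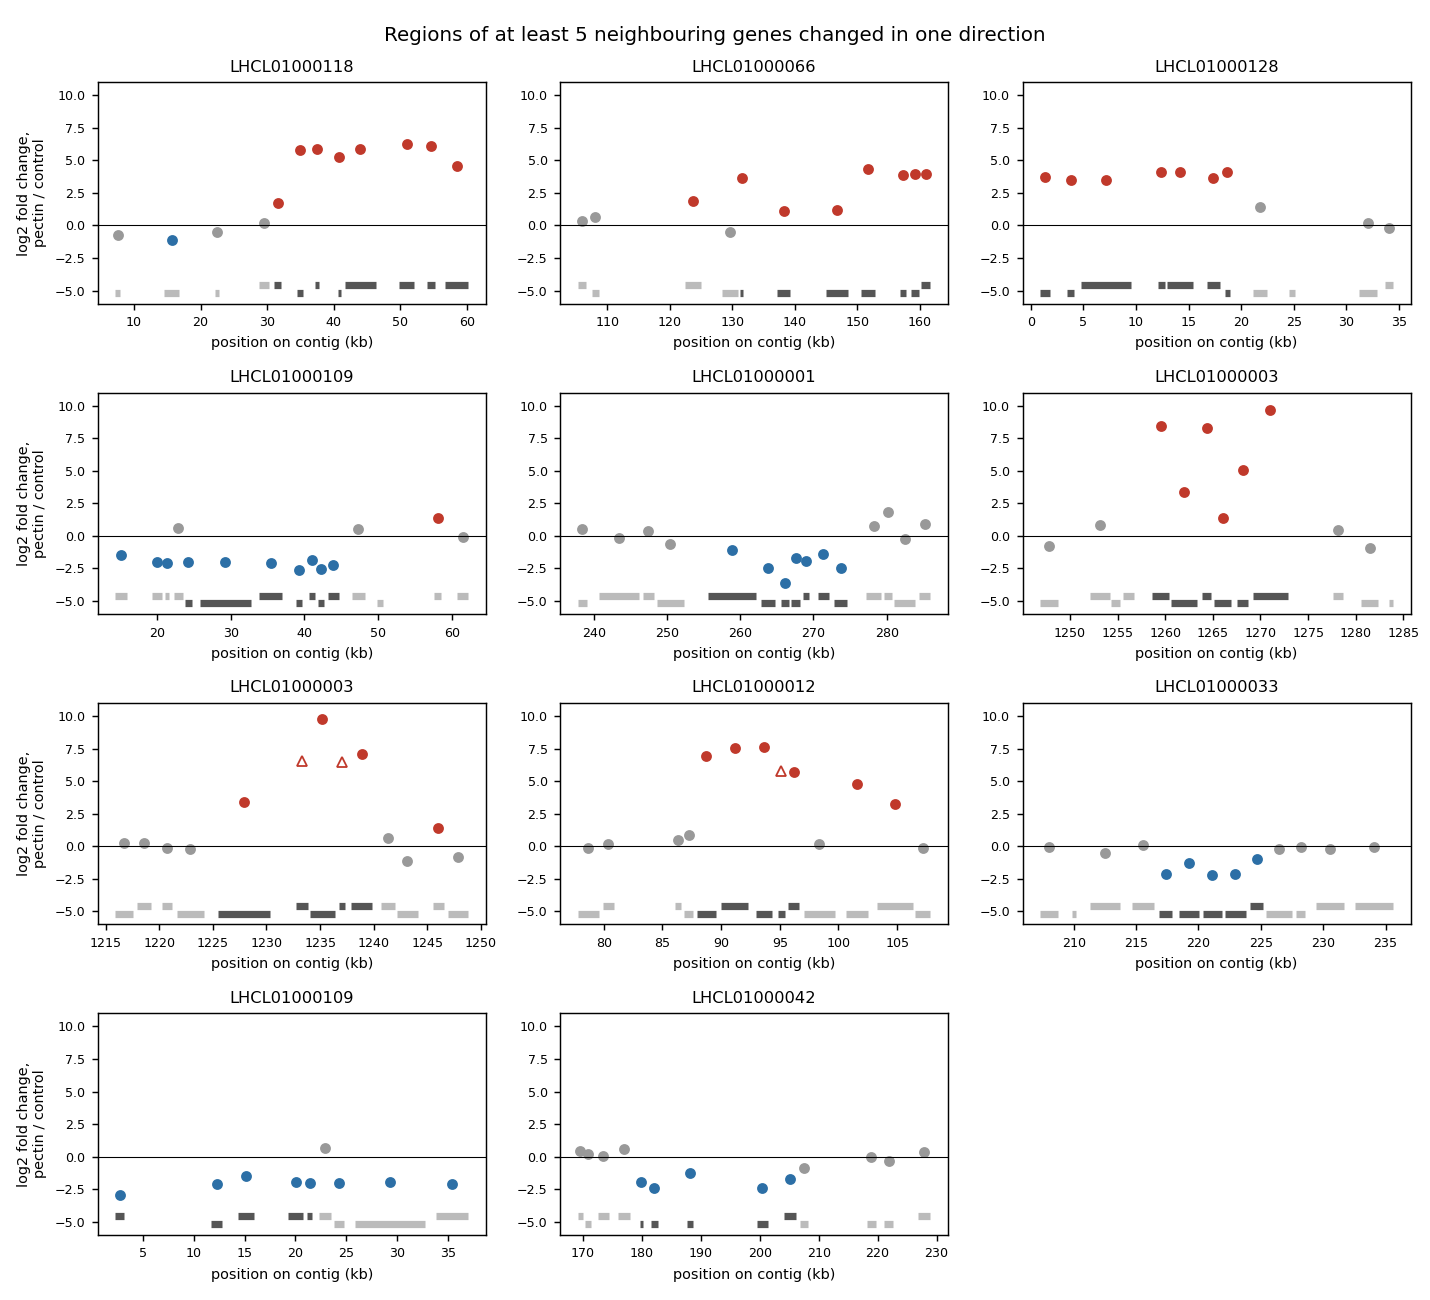
Log2 fold change of each gene, pectin over control (y axis), by position on its contig in kb (x axis) for the 11 runs of at least 5 genes with up to 4 genes on each side. Red and blue points are genes at least 2-fold higher or lower with an adjusted p under 0.05, grey points other tested genes, open triangles genes without reads in controls at their lower bound, and bars the genes by strand (plus above minus), dark inside the run; the 8-gene run on LHCL01000118 had a median rise of 57.1-fold.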

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

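The tests in this part were chosen after the values had been seen. Reads outside annotated exons are a part of the data that the gene counts do not use. Relative to the whole library, 22 genes had a higher share of such reads with pectin and 60 a lower share (edgeR, adjusted p under 0.05, 8062 genes tested). Each read type was scaled to its own library total. The fall of the share over whole libraries, from 17.7% to 15.1%, is thus largely taken out of these counts. In the 22 genes the median share went from 27.2% to 39.8%, and in the 60 genes from 24.1% to 11.7%. Of the 60, 36 were also at least 2-fold higher in exon reads, and of the 22, 7 were at least 2-fold lower. The same exon reads enter the share and the fold change, so a rise in exon reads lowers the share by construction unless reads outside exons rise as much, and no test of this overlap is given. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 82 genes, 1 split including the real one gave as many, and the highest other gave 4. All other splits mix control and pectin libraries in both groups, which by itself keeps their calls low, so no conclusion is drawn from them. Without control 2 the counts were 20 lower and 9 higher, without pectin 1 they were 28 and 10, without pectin 2 they were 23 and 11, and without pectin 3 the higher count was 12.

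Reads that run past gene ends would change single-exon genes as well, but 81 of the 82 genes had several exons while 20.8% of the tested genes had 1 (Fisher's exact test, two-sided p = 1.51e-07). This bears on the 82 genes only: over whole libraries the share of reads outside exons was lower with pectin in single-exon genes too, at 23.6 ± 2.21% in control and 20.4 ± 1.65% with pectin, beside 16.6 ± 1.69% and 14.1 ± 0.796% in genes with several exons (SD, n = 3 each, exact permutation p = 0.1 for each), so reads past gene ends stay open for that difference. A constant background of reads outside exons would lower the share wherever exon reads rise. Over all 474 tested genes at least 2-fold higher, of which these 36 are a part, reads outside exons rose as well, by a median log2 change of 1.36 (bootstrap interval 1.2 to 1.5) beside 1.68 for exon reads with TMM factors, and by 1.14 with library size only. For the 36 genes such a background stays open. In these the median log2 change was 1.63 for exon reads and 0.28 for reads outside exons (bootstrap interval 0.16 to 0.43) with TMM factors, but 0.0817 (interval −0.035 to 0.21) with library size only, so whether reads outside exons rose at all depended on the scaling. More complete splicing with pectin may also lower the share and was not tested gene by gene; exon-exon junction reads made up 38.9 ± 0.564% of exon reads of genes with several exons in control and 40.6 ± 1.17% with pectin (SD, n = 3 each, exact permutation p = 0.1). Over whole libraries and all genes the share of reads outside exons was 17.7 ± 1.85% in control and 15.1 ± 0.841% with pectin (SD, n = 3 each, exact permutation p = 0.1, the smallest this design allows; 10 library measures were compared).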

How the results depend on the processing

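The alternatives with unique exon reads, total gene reads and without control 1 and pectin 1 together, and every alternative for 16-fold changes and neighbours, were chosen after seeing the data. Against 844 higher and 642 lower genes, library size only gave 545 higher, a filter of 10 CPM 556 higher, DESeq2's Wald test 965 lower, a demand of at least 2-fold 558 higher, glmTreat against 1.5-fold 321 and 246, and an adjusted p under 0.01 gave 278 and 177. The other alternatives in scaling, filter and test stayed within 1.5 times. Leaving out 1 library gave 325 to 929 higher and 190 to 707 lower genes, with no called gene changing sign (0 in each of the 6 fits). Stricter thresholds lower such counts by construction, and a fit with 1 library fewer also has less power. Otherwise the cause was not tested. Without control 1 the counts were higher, at 929 and 707.

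For 558 and 504 genes at least 2-fold higher and lower, the 10 CPM filter gave 321 higher, glmTreat 321 and 246, and an adjusted p under 0.01 gave 272 and 174; leaving out 1 library gave 315 to 603 and 186 to 514. Genes at least 16-fold higher numbered 74 to 126 in all alternatives. The 11 genes at least 16-fold lower became 20 without filter, 5 with the 10 CPM filter, 6 with limma-voom and 5 at an adjusted p under 0.01, and 4 to 16 without 1 library. For 122 higher and 96 lower neighbouring pairs, the 10 CPM filter gave 70 and 54, DESeq2's Wald test 145 lower, glmTreat 81 and 48, and an adjusted p under 0.01 gave 64 and 29, and single left-out libraries as few as 71 and 29. Runs of at least 3 genes (23 and 18) numbered 13 higher with the 10 CPM filter, 8 lower with glmTreat and 11 and 6 at an adjusted p under 0.01. With library size only there were 17 runs higher and 26 lower, and 95 pairs higher and 141 lower. The direction with more runs and pairs thus reversed with that scaling. For pairs it also reversed with upper-quartile factors (107 higher, 112 lower), DESeq2's Wald test (134 and 145) and the replicate block (131 and 134). Runs higher and lower were then 20 and 20, 27 and 22, and 26 and 22.

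Replicate numbers are shared between groups, but they are not said to mark pairs, so the test set beforehand did not take them as pairs. The deviations of same-numbered libraries correlated at 0.478, 0.0732 and 0.432, which does not settle the question. The second principal component ordered the libraries of both groups from number 1 to number 3. The replicate block gave 1163 higher and 1060 lower genes. Controls 1 and 3 correlated best with their own number, and control 2 with pectin 3 (0.356). ZTR_09821 and ZTR_03362 kept direction and call in all 19 alternatives, while ZTR_00191 lost its call in 8 and ZTR_03733 in 5. Alternatives for gene lists were not run, since the lists could not be applied. At this depth and replicate number the simulated recovery of 2-fold changes was 36%, so counts may miss many small changes. The simulation changed far fewer genes than the 1486 called in the data, which makes its adjusted threshold stricter. Its 36% therefore need not hold for the data.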

Other observations

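Of the tests in this part, those of gaps between genes, of unique reads, of gene structure, of 16-fold changes and of splits were chosen after the values had been seen, as were the patterns themselves. Genes at least 2-fold higher with pectin had shorter coding sequences than the genes not called at that size, with medians of 1185 and 1383 bp (permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 4e-05 over 4 tests). The mean difference in log2 coding length was −0.209, and it was −0.119 without pectin 1, −0.139 without control 2 and −0.113 without filter. At a threshold of 0.01 for the genes this difference missed 0.05 (permutation, adjusted p = 0.0553, with 4e-05 to 0.0553 over all alternatives). Single-exon genes made up 17.6% of them and 21.4% of the other genes, which did not pass after adjustment (Fisher's exact test, adjusted p = 0.064); it passed without filter, with limma-voom, without control 3 and without pectin 3 (Fisher's exact test, adjusted p = 0.0401, 0.0407, 0.00235 and 0.000473, in a range up to 0.624). For genes at least 2-fold lower neither test passed (adjusted p = 0.457 for single-exon genes by Fisher's exact test and 0.763 for coding length by permutation), although coding length passed with library size only, without filter and without pectin 2 (permutation, adjusted p = 0.0493, 0.011 and 0.00976, in a range up to 0.803).

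Neighbouring genes changed in one direction more often than random placement gave. There were 122 neighbouring pairs of genes that rose, against 28.7 expected, and 96 of genes that fell, against 23.4 (permutation p = 2e-05, the smallest that 100000 placements give, for each), while 19 pairs went opposite ways against 52.0 expected. The placements take genes as separate units, so this p does not measure the spread between cultures. Neighbours that vary together between cultures would also be called together, so it says that calls are clustered, not that pectin is the cause. Reads running from a gene into the next one would make close neighbours alike, but pairs more than 1000 bp apart were at least 3.82 times as frequent as random placement among all tested genes gave, in either direction (43 and 49 pairs), and 3.68 times for rises with placement within classes of level. Reads shared by near-identical copies were argued against by pairs with at least 99% unique reads in both genes, at least 4.05 times as frequent (7765 of the 7782 pairs of tested neighbours qualify). Contigs with at least 100 genes held 53 of 122 rising and 53 of 96 falling pairs, at 3.03 and 3.72 times random placement. Short contigs that change as a whole therefore cannot be the only source of pairs. Over all contigs the ratios were 4.25 and 4.1, so the excess was larger on shorter contigs, and a part from them stays open. Similar read depth of neighbours was argued against by placement within 10 classes of level, at 4.19 times or more. A candidate explanation is that groups of adjacent genes respond together to pectin, which stays a hypothesis found and tested on the same data. Counts of pairs fell to 71 higher and 29 lower without pectin 2. They fell to 76 and 58 without control 2 and to 49 lower without pectin 1. Genes at least 2-fold changed fell in these fits as well, to 315 higher and 186 lower, to 321 and 316, and to 292 lower. Random placement was not run for these fits, so whether pairs fell relative to it is not known.

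Rises of at least 16-fold outnumbered falls of that size by 108 to 11 in fitted fold changes, or by 107 to 11 with genes without control reads at the floor. Scaling would have to bring both numbers together, but over 4 scalings there were at most 15.7 falls per 100 rises. These scalings moved the median log2 fold change only to −0.21 from −0.0061, too little to level the numbers, so they could not have come out otherwise. In the main fit 62 genes rose by at least 5 and 38 fell by at least 3 on the log2 scale. With the same calls, a shift of 1 would thus not level them, and larger shifts were not tried. A detection floor could hide large falls of weakly expressed genes; among the 4020 tested genes with at least 50 CPM in the higher group there were 52 rises and 1 fall, or 1.92 per 100. Without control 1 the number of falls was 7 and without pectin 2 it was 4. Why rises were larger was not tested. For the counts of genes called, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 1486 genes, 1 split including the real one gave as many, and the highest other gave 0 in edgeR. Every other split mixes control and pectin libraries in both groups, which puts the pectin difference into the spread within groups. That by itself keeps their calls low, so no conclusion is drawn from these numbers. At an unadjusted p under 0.05 the real split had 2875 genes and the highest other 1282. That other split set control 1, pectin 1 and pectin 2 against control 2, control 3 and pectin 3, as the sign of the second principal component did. The remaining splits had 27 to 301 genes. What sets these libraries apart within both groups was not tested. No other tool was run on the splits.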
